A study of Homo sapiens with 6 samples.

How the data were processed

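Poly(A) RNA from Mon-Mac-6 cells, an established human line of monocytic acute leukaemia cells, was measured by paired-end RNA sequencing after 48 h with DMSO, the vehicle, or with 500 nM WD6305. The series title calls WD6305 a PROTAC directed at METTL3, a class of molecule that brings a target protein to an E3 ubiquitin ligase. There were 6 libraries, 3 per group, and each was placed in its group by the treatment recorded in its label. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a dUTP second strand. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty.

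The deposited table holds 31853 Ensembl genes, with an estimated count and an FPKM value for each of the 6 libraries, and 0 further columns of samples. Per the submitters' processing notes, fastp, HISAT2, StringTie and edgeR were used with the GRCh38 build, and their versions and settings are not given in the sources used here. The deposited estimated counts are whole numbers and sum to between 64525948 and 71155346 per library. Among low genes they pile up at multiples of 4: in each library between 1071 and 1176 genes had a count of 4, against 553 to 636 genes with a count of 3 and 357 to 380 with a count of 5. If 1 read pair is worth 4 counts, the number of read pairs per library is 4-fold below these totals. The counts would then overstate the number of fragments, so counting error was taken from the spread between libraries. The FPKM values were normalised by the authors to transcript length and library size, per the file headers, and are rounded to 2 decimals. Gene coordinates are those of the deposited table on GRCh38.

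The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The design was written for FPKM values, with limma as the test, and named edgeR as the main test should counts be present. The table held both, so edgeR on the deposited estimated counts gave the main result and limma on FPKM was an alternative. Counts were already whole numbers, so rounding left them as they were. Genes were kept with filterByExpr, which left 18138. Libraries were scaled with TMM factors, which lay between 0.987 and 1.02, and the quasi-likelihood test in edgeR 4.0.16 under R 4.3.3 compared WD6305 with DMSO, two-sided, with no replicate block. P-values were adjusted over all tested genes by the Benjamini-Hochberg method at a threshold of 0.05. Levels are CPM, the counts relative to the TMM-scaled library size, given as mean ± SD over the 3 libraries of a group. The standard error of a log2 fold change was taken from the quasi-likelihood F value. The common dispersion corresponded to a biological coefficient of variation of 20.8%.

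The 35 gene lists held 904 gene entries, of which 876 were matched to the table by symbol, older symbols included. They cover the m6A machinery, leukaemia programmes, myeloid differentiation, the cell cycle, growth and metabolism, stress responses, innate immunity, antigen presentation, organelles, degrader-related E3 ligase components and markers of other cell types. Each was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists. Camera with an estimated correlation and fry were run beside it. Named genes were METTL3 and the other writer complex members, the 10 largest rises and 10 largest falls, and up to 4 members per list with the smallest adjusted p. For the largest changes, a gene needed a symbol, an adjusted p under 0.05, a mean FPKM of at least 1 in the higher group and no overlap between the groups. Some genes that met the rule are not named. Where a count in a list was 5 or less, members outside that rule are mostly named too, and these, like all genes named in the account of keratin and collagen transcripts, were chosen after their values were seen.

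Library similarity was computed as Pearson correlations and principal components of log2(FPKM + 1) over 11144 genes with an FPKM of at least 1 in at least 3 libraries. Counts divided by 4 were compared between libraries within a group by chi-square, over genes with at least 20 such counts in the 2 libraries together. The chi-square per degree of freedom was 3.77 to 10.5 for the 6 pairs within groups, lowest for WD6305 2 and 3. If 1 read pair is worth 4 counts, counting noise alone gives a value near 1, so each of the 6 pairs differed by more than that.

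The fits were tested on simulated data. Counts were drawn for the real genes with known changes, and 17546 genes entered the test, of which 188 carried a change. In the real data 4249 genes were called, so the adjusted threshold was stricter in the simulation. The shares recovered there do not give the share of real changes found. The simulated comparison of WD6305 with DMSO recovered 30.2% of genes changed 1.5-fold, 54.7% of genes changed 2-fold and 88.5% of genes changed 4-fold. Of its 117 calls, 7.69% were unchanged genes. A simulated list of 30 genes raised 1.3-fold gave a camera p of 3.96e-28, and 3% of 200 unchanged lists fell under 0.05. Among the real lists past the threshold, the estimated inter-gene correlation ran from -0.025 for class II antigen presentation to 0.74 for cytosolic ribosomal proteins. Correlation between genes was not varied in the simulation, so the 3% does not give the error rate of camera for correlated lists.

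Alternatives fixed in advance were limma on FPKM with pseudocounts of 1, 0.1 and 0.5, other filters, quantile, TMM and median scaling, limma without a trend and with robust spread, a replicate block, DESeq2 1.42.0, a fold threshold and leaving out each library in turn. Chosen after seeing the data were RLE factors, library sizes alone, counts divided by 4, a term for the libraries that carried keratin transcripts and a fit of those 4 libraries alone. Transcript length, GC content and DRACH motifs, the sequence context of m6A, were taken from GENCODE 29 on GRCh38 for the transcript with the longest coding sequence of each gene. Motifs within 100 bases of an exon junction were left out. Annotated terms of 10 to 300 genes came from the deposited table. Figures were drawn with matplotlib 3.10.9.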

Results

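The series compared Mon-Mac-6 cells given 500 nM WD6305 for 48 h with cells given DMSO, to ask how gene expression changes when the cells meet a degrader directed at METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on messenger RNA. There were 3 libraries per group. Deposited counts summed to 71155346, 66525685 and 67483820 in DMSO 1, 2 and 3 and to 64525948, 69726451 and 67352561 in WD6305 1, 2 and 3. Among low genes the counts pile up at multiples of 4. Between 23274 and 23933 genes had a count above 0 in a library. Mitochondrially encoded genes took 4.10% to 5.11% of counts.

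METTL3 RNA was 1.16-fold higher under WD6305. METTL3 lies on the minus strand of chromosome 14 from 21498133 to 21511342 (GRCh38), and its level was 67.3 ± 2.86 CPM with DMSO and 78.0 ± 1.88 CPM with WD6305 (mean ± SD, n = 3 libraries per group). The log2 fold change was 0.21 (SE 0.05, adjusted p = 0.0218, edgeR quasi-likelihood test), with every WD6305 library above every DMSO library. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The call was lost at adjusted p = 0.0501 to 0.0931 (edgeR) when DMSO 2 or any single WD6305 library was left out, and at 0.0588 (edgeR) in the 4 libraries with keratin transcripts alone. With the replicate number as a block it was lost at 0.0584 (edgeR). The sign was kept in each. The data used here hold no protein measurement.

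Of the 8 members of the m6A writer complex, 5 rose and 3 did not pass the test. RBM15, an adaptor that brings the complex to RNA, rose from 38.1 ± 3.23 to 57.2 ± 1.13 CPM (log2 fold change 0.59, SE 0.07), and METTL14, the partner of METTL3, rose by 0.44 (SE 0.09). WTAP and CBLL1 rose by 0.21 and 0.24. ZC3H13, VIRMA and RBM15B had log2 fold changes of 0.42, 0.20 and 0.06 and did not pass in edgeR. ZC3H13 passed in DESeq2 (adjusted p = 0.00649) and in edgeR with a term for the libraries with keratin transcripts (adjusted p = 0.00921). ZC3H13 and VIRMA passed in edgeR without DMSO 3 (adjusted p = 0.000741 and 0.00293) and in the 4 libraries with keratin transcripts (0.00168 and 0.00537). WTAP lost its call without DMSO 2, WD6305 1 or WD6305 3 (edgeR adjusted p = 0.0640 to 0.0730), and CBLL1 without any 1 library (0.0507 to 0.109), with no filter, the replicate block, library sizes alone or the 4 libraries with keratin transcripts (0.0510 to 0.117). Adjusted over the list alone, 7 members were higher. The list passed camera at adjusted p = 0.00577, and had adjusted p = 0.188 with an estimated correlation. Among genes with an FPKM of at least 5 it missed the threshold (camera adjusted p = 0.0860).

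Across the transcriptome, 4249 of 18138 tested genes changed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 2218 higher and 2031 lower under WD6305. Which direction held more genes depended on the processing. With library sizes alone 1998 were higher and 2334 lower (edgeR), and with limma on log2(FPKM + 1) 1921 and 2270, while DESeq2 gave 2520 and 2483. Most changes were small. The median absolute log2 fold change of the changed genes was 0.42, or 1.34-fold, and 418 genes changed at least 2-fold, 235 of them higher and 183 lower. The groups did not overlap for 7394 tested genes, or 40.8%, where chance gives 10%. Limma on FPKM, whose pseudocount shrinks the folds of low genes, called 57 to 160 genes at least 2-fold changed. The count of changed genes was 2756 without WD6305 3.

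Replicates were more alike than groups. Pearson's r of log2(FPKM + 1) across 11144 genes was 0.989 to 0.993 within groups and 0.974 to 0.980 between them, as a description across genes, which are not independent replicates. The first principal component held 56% of the variance and separated the groups. The second held 16.3% and set DMSO 3 and WD6305 1 apart from the other 4 libraries.

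**Figure D1:**
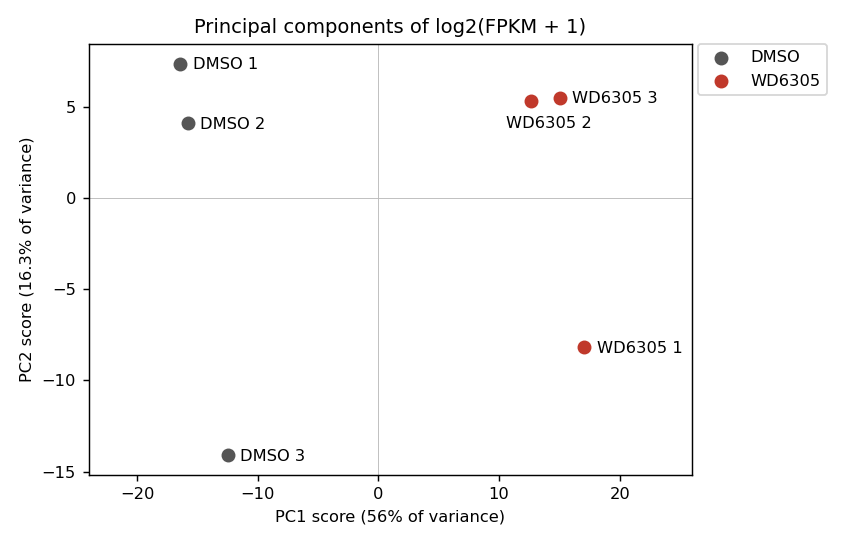
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1), coloured by group, 1 point per library. DMSO libraries lie at negative and WD6305 libraries at positive scores of the first component, which holds 56% of the variance.

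The strongest rise among named genes was in HLA-DRA, the alpha chain of the class II antigen-presenting molecule HLA-DR, which went from 2.60 ± 0.513 to 24.5 ± 0.880 CPM, or 9.41-fold (log2 fold change 3.23, SE 0.14, adjusted p = 2.22e-05, edgeR quasi-likelihood). LTC4S, the synthase of leukotriene C4, rose 4.53-fold, and TLR8, an endosomal receptor for RNA, rose 3.76-fold to 11.5 ± 1.95 CPM. ACSM3 rose 3.56-fold, DEFB1, a beta-defensin, rose 3.37-fold to 34.0 ± 4.61 CPM, and AOC1, a diamine oxidase, rose 3.32-fold. DHRS9 and CLEC4D, a C-type lectin of myeloid cells, rose 3.09-fold and 3.05-fold. PCP2 and B3GALT4 rose by 1.87 and 1.78 on the log2 scale, PCP2 from a level of 0.261 ± 0.0266 CPM.

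IL7R, the interleukin-7 receptor alpha chain, fell from 10.4 ± 0.755 to 1.93 ± 0.759 CPM (log2 fold change -2.43, SE 0.25, adjusted p = 0.000313, edgeR quasi-likelihood). CSPG4, a surface proteoglycan, fell from 25.5 ± 2.25 to 6.42 ± 1.04 CPM, 3.98-fold lower. The immunoglobulin heavy chain genes IGHM and IGHA1 had log2 fold changes of -1.60 and -2.17, and reads of IGHA1 may be shared with its near-identical copy IGHA2. GZMH (-1.94), RGS16 (-1.89), JAML (-1.61) and FLRT1 (-1.56) fell too on the log2 scale. SNORD17, a small nucleolar RNA that a poly(A) library samples poorly, had counts of 18, 17 and 40 with DMSO and 0, 1 and 3 with WD6305. MIA-RAB4B, a readthrough gene sharing reads with its component genes, had counts of 171, 132 and 163 with DMSO and 0, 35 and 0 with WD6305, so its fold is uncertain. SNORD17 lost its call without DMSO 3 or WD6305 2 (edgeR adjusted p = 0.0653 to 0.0692), and MIA-RAB4B without any 1 library but WD6305 2 (0.0662 to 0.0962), with no filter (0.125), with the replicate block (0.0516) and in DESeq2 (0.192). Both lost it in the 4 libraries with keratin transcripts (edgeR adjusted p = 0.0886 and 0.0770).

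**Figure D2:**
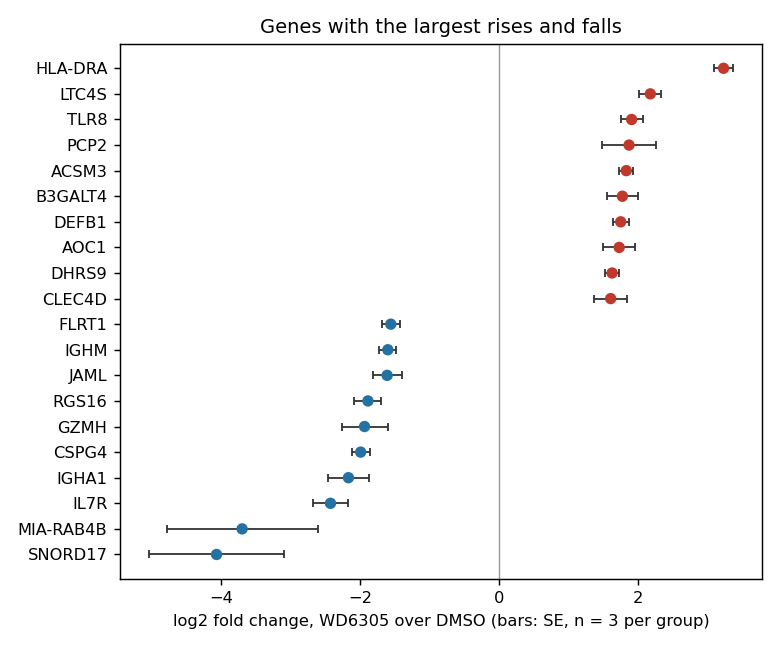
Log2 fold changes of WD6305 over DMSO (x axis) with SE bars, n = 3 libraries per group, for the 10 largest rises and 10 largest falls. HLA-DRA stands at 3.23. SNORD17, with counts of 0 to 3 under WD6305, and MIA-RAB4B, with counts of 0, 35 and 0, have wide bars.

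Among the 35 lists, 16 passed camera, 8 toward higher and 8 toward lower expression, and 3 of them passed with an estimated correlation: the granule, class II and MYC-target lists. Myeloid progenitor and granule genes, which encode the proteases and antimicrobial proteins stored by granulocyte and monocyte precursors, rose in 13 of 14 tested members, with a median log2 fold change of 0.82. AZU1 (azurocidin) rose from 747 ± 31.4 to 1759 ± 95.3 CPM, ELANE (neutrophil elastase) from 1699 ± 83.6 to 3177 ± 40.7 CPM, and CSF3R, the receptor for G-CSF, from 126 ± 10.2 to 279 ± 3.74 CPM. MS4A3 rose by 0.85 on the log2 scale. MPO (myeloperoxidase) alone fell, with a log2 fold change of -0.35. Adjusted over the list alone the counts were again 13 and 1. The camera adjusted p was 2.1e-39, and adjusted p = 0.0316 with an estimated correlation.

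Class II antigen presentation rose in 8 of 11 members with none lower (median log2 fold change 1.13), and in 10 adjusted over the list alone. CD74, the invariant chain, rose from 117 ± 3.31 to 255 ± 7.09 CPM, and CIITA, the transactivator of class II genes, from 8.00 ± 1.16 to 17.7 ± 3.89 CPM. HLA-DMA rose 2.18-fold. The list passed camera at adjusted p = 9.5e-14, and adjusted p = 0.0223 with an estimated correlation. Of 19 class I genes, 10 rose and 1, TAP2, fell (log2 fold change -0.16), against 12 and 2 adjusted over the list alone. HLA-B and HLA-C, whose reads may be shared among similar genes, rose 1.46-fold and 1.36-fold, and ERAP1 rose 1.45-fold. The class I list had camera adjusted p = 3.17e-05, and adjusted p = 0.188 with an estimated correlation.

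Monocyte and macrophage genes moved both ways. Of 22 tested, 12 rose and 4 fell, the same counts as adjusted over the list alone. CD68, a macrophage lysosomal protein, rose 2.25-fold, the calgranulins S100A9 and S100A12 rose 1.72-fold and 2.43-fold, and the integrin ITGAX rose 2.23-fold. Among the members that fell were CD163, a scavenger receptor (log2 fold change -1.38), CD14 (-0.37) and CD86 (-0.37). In camera the list had adjusted p = 1.36e-06, and adjusted p = 0.114 with an estimated correlation. Lysosomal genes rose in 21 of 33 and fell in 3 (median 0.39), against 24 and 3 adjusted over the list alone, with GRN at 586 ± 17.4 and 995 ± 24.0 CPM and CTSA, ASAH1 and LIPA rising 1.61-fold, 1.56-fold and 1.53-fold. CTSL, NPC1 and ATP6V1H fell. The lysosome list had camera adjusted p = 1.63e-19, and adjusted p = 0.155 with an estimated correlation.

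MYC, a transcription factor that drives growth, fell from 410 ± 14.8 to 317 ± 5.43 CPM (log2 fold change -0.37, SE 0.04, adjusted p = 0.000664, edgeR quasi-likelihood). In the list of MYC targets and ribosome biogenesis, 34 of 40 fell and 0 rose, with 37 lower adjusted over the list alone. MYBBP1A, RRP9 and BOP1, which act in ribosome assembly, had log2 fold changes of -0.81, -0.83 and -0.69, and ODC1, the first enzyme of polyamine synthesis, had -0.68. The median was -0.40, with camera adjusted p = 6.62e-29, and adjusted p = 0.0223 with an estimated correlation. Of 31 proteasome genes 27 fell and 0 rose (28 lower adjusted over the list alone), with PSMD3, PSMC3, PSMB2 and PSMD2 between -0.59 and -0.46. Camera gave adjusted p = 1.13e-18, and adjusted p = 0.155 with an estimated correlation.

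Metabolic and biosynthetic lists fell as well. ATF4 targets of the integrated stress response fell in 17 of 31 and rose in 3 (CEBPG, CEBPB and VLDLR), against 19 and 3 adjusted over the list alone. ATF4 itself fell by 0.54 on the log2 scale, and SLC7A5, PHGDH and GARS1 fell by 0.73, 0.70 and 0.45. The list had camera adjusted p = 1.27e-07, and adjusted p = 0.188 with an estimated correlation. Of 43 nuclear genes of oxidative phosphorylation 24 fell and 2, COX6A1 and UQCRFS1, rose (26 and 2 adjusted over the list alone). CYC1, NDUFS1, ATP5F1A and NDUFS3 were among those that fell. The list passed camera at adjusted p = 3.28e-08, and adjusted p = 0.429 with an estimated correlation. Glycolysis genes fell in 10 of 19, or 14 adjusted over the list alone, with HK1, HK2 and LDHA at -0.34, -0.37 and -0.38, while HK3, the hexokinase of myeloid cells, rose 2.57-fold. The camera adjusted p was 2.68e-05, and adjusted p = 0.337 with an estimated correlation. Cytosolic ribosomal protein genes fell in 12 of 62 (10 adjusted over the list alone) and rose in 0, with RPL5, RPL24, RPL8 and RPL7 between -0.40 and -0.29, of which RPL8 lost its call without WD6305 3 (edgeR adjusted p = 0.0501). In camera the list had adjusted p = 4.02e-05, and adjusted p = 0.659 with an estimated correlation.

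Other RNA methyltransferases fell in 4 of 13 members and rose in 1, METTL4, against 7 and 1 adjusted over the list alone. TRMT61A, a tRNA m1A methyltransferase subunit, fell from 24.6 ± 1.57 to 12.3 ± 0.656 CPM. METTL1 and WDR4, which together make the tRNA m7G methyltransferase, had log2 fold changes of -0.71 and -0.69, and NSUN2, an m5C methyltransferase, had -0.35. Camera gave adjusted p = 0.00191, and adjusted p = 0.188 with an estimated correlation. Mitotic genes fell in 14 of 40 and rose in 0, the same adjusted over the list alone, with a median of -0.10. CDC20, the activator of the anaphase-promoting complex, fell from 258 ± 18.9 to 151 ± 9.76 CPM, and CCNB2, BIRC5 and PTTG1 fell by 0.31, 0.38 and 0.44. The list passed camera at adjusted p = 0.00837, and adjusted p = 0.155 with an estimated correlation. It missed the threshold without DMSO 3 (0.0865), in the 4 libraries with keratin transcripts (0.0859), under quantile scaling (0.0647) and among genes with an FPKM of at least 5 (0.0766, camera adjusted p in each).

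Genes of the unfolded protein response, many of them chaperones of the endoplasmic reticulum, rose in 10 of 19 members (13 adjusted over the list alone), with SDF2L1 up 1.94-fold and PDIA4 and SEL1L up by 0.37 and 0.34. XBP1, the transcription factor of this response, and HYOU1 fell by 0.35 and 0.24. In camera the list had adjusted p = 0.0112, and adjusted p = 0.155 with an estimated correlation, and it missed the threshold among genes with an FPKM of at least 5 (0.142). Replication-dependent histone genes rose in 9 of 28 and fell in 0, the same adjusted over the list alone, with H2BC12, H2BC5, H1-2 and H2AC18 up 1.72-fold, 2.00-fold, 1.82-fold and 2.16-fold. These messages mostly lack a poly(A) tail and are near-identical copies, so their counts in poly(A) libraries are uncertain. Camera gave adjusted p = 0.000303, and adjusted p = 0.109 with an estimated correlation.

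**Figure D3:**
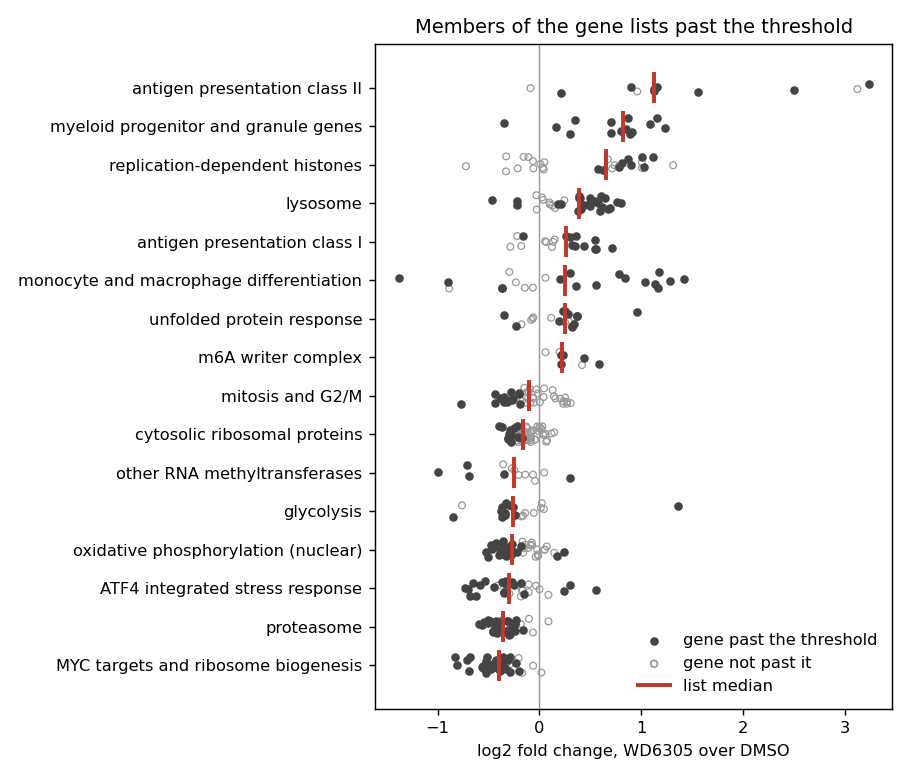
Log2 fold changes of WD6305 over DMSO (x axis) for the members of the 16 lists past the threshold (y axis), filled where the gene passed the edgeR test and open where it did not, with a red bar at each list's median. Medians run from -0.40 for MYC targets to 1.13 for class II antigen presentation.

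Leukaemia genes reported by earlier studies as m6A-regulated did not pass as a list (camera adjusted p = 0.856). Of 13 tested, 2 fell, MYC and ASB2, and 2 rose, MYB among them, against 3 lower and 4 higher adjusted over the list alone. ASB2 lost its call without DMSO 2, WD6305 2 or WD6305 3 (edgeR adjusted p = 0.101 to 0.134), with no filter (0.0663) and with the replicate block (0.0792), and MYB without DMSO 2 (0.0523). The HOXA and MEIS1 programme held 3 genes that rose (HOXA3, MYB and ZEB2) and 3 that fell (HOXA7, HOXA6 and SATB1) of 22, with 4 and 3 adjusted over the list alone and camera adjusted p = 0.856. ZEB2 lost its call without any 1 library but DMSO 3 (edgeR adjusted p = 0.0579 to 0.0823), with no filter (0.0637) and in limma without a trend (0.0510), and HOXA3 in the 4 libraries with keratin transcripts (0.0630). Among 14 m6A erasers and readers, YTHDF2 and YTHDC1 rose and HNRNPC, PRRC2A and HNRNPA2B1 fell, with 5 higher and 3 lower adjusted over the list alone and camera adjusted p = 0.856. YTHDC1 lost its call without DMSO 1, DMSO 2, WD6305 1 or WD6305 2 (edgeR adjusted p = 0.0517 to 0.0711). The median of that list was 0.01 and its camera direction was lower.

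Growth arrest and death genes had no common direction. Of 25 p53 targets 5 rose and 6 fell (5 and 8 adjusted over the list alone), with TP53INP1 up 2.96-fold, FAS up 2.18-fold, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, and TNFRSF10B down by log2 fold changes of -0.83 and -0.51. The camera adjusted p was 0.588. Of 32 apoptosis genes, 7 rose, CFLAR and BIRC2 among them, and 3 fell, TNFRSF10B, BAK1 and CYCS, the same counts as adjusted over the list alone (camera adjusted p = 0.406). Among 6 kinase inhibitor genes CDKN2C and CDKN2B rose and CDKN1A fell, as adjusted over the list alone, with CDKN2A at a log2 fold change of 0.11 that did not pass in edgeR but passed in limma under quantile scaling (adjusted p = 0.0208), and camera adjusted p = 0.609. CDKN2C lost its call without WD6305 3 (edgeR adjusted p = 0.0577). Genes of DNA replication fell in 11 of 43, RRM2, CDC6, TYMS and UHRF1 among them, and rose in 5 (E2F8, ORC1, FEN1 and GINS3 among them), with 12 and 6 adjusted over the list alone and camera adjusted p = 0.0929, or 0.0380 with no filter on low counts.

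Interferon-stimulated genes rose in 10 of 44 and fell in 2, USP18 and LGALS3BP, the same adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0794), while it passed without DMSO 3 (0.0194) or WD6305 1 (0.0411) and with limma on FPKM (0.0140). STAT2 and IRF9, which form the transcription factor of the type I interferon response, rose 1.62-fold and 1.85-fold, and IRF7 and SAMD9L rose 1.36-fold and 1.79-fold. Genes that sense double-stranded RNA rose in 4 of 15, IRF7, IRF3 and DHX58 among them, or 5 adjusted over the list alone, and fell in 0 (camera adjusted p = 0.0517). Without 1 library other than DMSO 3, IRF3 and DHX58 lost their calls in some tests (edgeR adjusted p = 0.0586 to 0.0894), as they did with the replicate block (0.0575 and 0.0633) and DHX58 in the 4 libraries with keratin transcripts (0.0775). The list of sensors passed without DMSO 3 (0.0452), WD6305 1 (0.0363) or WD6305 3 (0.0494) and with limma on FPKM (0.0223, camera adjusted p in each). Of 34 NF-kB response genes 8 rose, TNFAIP3 and TLR2 first, and TNF, IER3 and IL1B fell, with 9 and 4 adjusted over the list alone. TNF was 2.21-fold lower. That list had a median of 0.02, a mean of -0.08 and camera adjusted p = 0.769. Cytokine feedback genes fell in 7 of 21, with PIM1, PIM3, DUSP2 and SPRY4 first, and SOCS5 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.0603, and 0.0465 without DMSO 1 and 0.0409 without WD6305 2). DUSP2 and SPRY4 lost their calls in the 4 libraries with keratin transcripts (edgeR adjusted p = 0.0586 and 0.0533).

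Cholesterol synthesis genes fell in 9 of 25, SREBF2 and HSD17B7 among them, and SC5D and STARD4 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.0577, and 0.0368 without DMSO 2 and 0.00508 without WD6305 2). The cholesterol list also passed with DESeq2 (0.0461), the replicate block (0.0489), no filter (0.0198) and library sizes alone (0.0312, camera adjusted p in each). HSD17B7 lost its call without WD6305 3 (edgeR adjusted p = 0.0514). Hypoxia targets went both ways, 5 of 23 higher (NDRG1, CITED2, EGLN1, KDM3A and P4HA1) and 6 lower (SLC2A1 first), with 5 and 7 adjusted over the list alone and camera adjusted p = 0.786. Their median of -0.16 and mean of 0.01 differed in sign. Immediate early genes rose in 5 of 22 (FOSL2, KLF10, BTG2, KLF2 and KLF4) and FOSL1 and NR4A1 fell, the same adjusted over the list alone, with NR4A1 losing its call in the 4 libraries with keratin transcripts (edgeR adjusted p = 0.0511). Their median of -0.04 was below 0 while the mean of 0.01 and the camera direction were above (adjusted p = 0.856). Among 15 E3 ligase components used by degraders, DDB1, CDC34 and CUL4A fell, also adjusted over the list alone, CRBN had a log2 fold change of 0.28 that did not pass in edgeR (adjusted p = 0.0737) and passed in DESeq2 (adjusted p = 0.0479), and the list had camera adjusted p = 0.207. Without WD6305 3, CDC34 and CUL4A lost their calls (edgeR adjusted p = 0.0612 and 0.124), and CUL4A also without DMSO 2, DMSO 3 or WD6305 2 (0.0647 to 0.125), with no filter (0.0748), with the replicate block (0.0831) and in limma under quantile scaling (0.154).

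Of the 13 mitochondrially encoded genes 0 passed the edgeR test, also adjusted over the list alone, with 1 at an unadjusted p under 0.05, while DESeq2 passed 1, MT-CO1, and limma on log2(FPKM + 1) passed 0 (camera adjusted p = 0.217). Without DMSO 2, MT-CO1 (edgeR adjusted p = 0.0347) and the list (camera adjusted p = 0.0223) passed toward higher expression. Among genes with an FPKM of at least 5, MT-ND5 and MT-ND2 passed in edgeR (adjusted p = 0.0492 and 0.0498). MT-CO1 was at 11130 ± 1612 and 13240 ± 1276 CPM and MT-ND5, MT-ND2 and MT-ND6 had log2 fold changes of 0.17, 0.18 and 0.13, with signs for MT-CO1 and MT-ND2 that turned under quantile scaling, where limma passed MT-ND2 as lower (adjusted p = 0.0120). Of 7 tested erythroid and megakaryocyte markers 0 passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma on log2(FPKM + 1), and EPOR at 13.1 ± 1.16 and 14.4 ± 0.652 CPM (camera adjusted p = 0.602). Of 8 lymphoid markers 1, TRAC, fell to 0.999 ± 0.310 CPM, a call lost without DMSO 2 (edgeR adjusted p = 0.0669) or WD6305 3 (0.0508) and in the 4 libraries with keratin transcripts (0.0636), while NKG7 stood at 164 ± 15.6 and 152 ± 14.8 CPM (camera adjusted p = 0.470). Of 10 fibroblast and epithelial markers KRT18 and KRT8 fell and MUC1 rose (camera adjusted p = 0.217, and 0.0211 without DMSO 1), and MUC1 lost its call without WD6305 3 (edgeR adjusted p = 0.0572). The counts for these 3 lists were the same adjusted over the list alone.

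Libraries differed in transcripts of other cell types in a way the groups do not explain. KRT5, a keratin of basal squamous epithelium, was at 63.4 to 79.3 CPM in DMSO 1, DMSO 2, WD6305 2 and WD6305 3 and at most 0.131 CPM in DMSO 3 and WD6305 1. KRT6A, KRT17 and COL17A1 followed the same split. COL1A1, a collagen of fibroblasts, was at 33.5 CPM in WD6305 1 and at most 2.60 CPM in the other 5 libraries, and COL1A2 had 460 counts there and 0 elsewhere. The DMSO and WD6305 groups each held 2 libraries with keratin transcripts and 1 without. The split is balanced over the groups, so a term for it takes little from their difference. With this term 4957 genes passed (edgeR), 4224 of the 4249 changed genes among them, and 16 lists passed camera. In the 4 libraries with keratin transcripts alone, 4124 genes and 17 lists passed. These genes held 3353, or 78.9%, of the 4249.

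**Figure D4:**
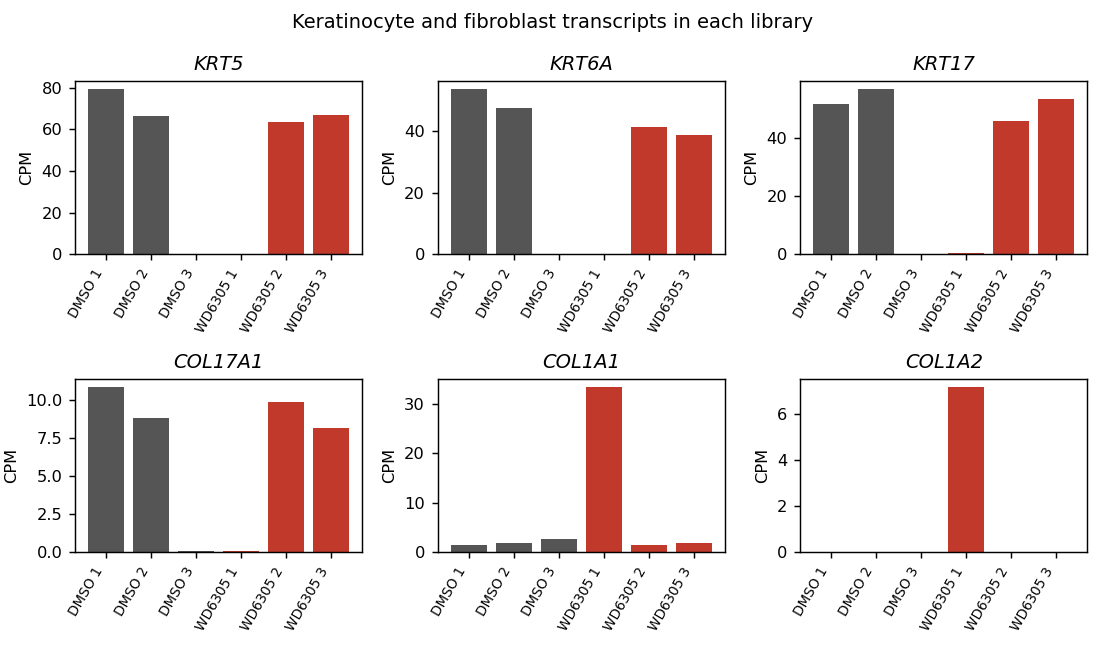
CPM (y axis, from 0, a separate scale per gene) of 4 keratinocyte and 2 fibroblast genes in each of the 6 libraries, 1 bar per library. KRT5 lies between 63.4 and 79.3 CPM in 4 libraries, and COL1A1 reaches 33.5 CPM in WD6305 1.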

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

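The tests with RLE factors, library sizes alone, counts divided by 4, the keratin term and the 4 keratin-carrying libraries were chosen after seeing the data. Of the 140 genes other than METTL3 that met the naming rule and passed, 118 kept their direction and call in every alternative that tested them, as did 13 of the 16 lists in camera at the preset correlation, and none turned sign. Without 1 library, 18 of these genes and the mitosis list lost the call in at least 1 such test, and 6 other lists passed. With no filter on low counts 21 lists passed, the interferon, double-stranded RNA, cytokine feedback, cholesterol and DNA replication lists being added. The mitosis list also missed the threshold under quantile scaling, in the 4 keratin-carrying libraries and among genes with FPKM of at least 5, as did the m6A writer and unfolded protein response lists in the last. DESeq2 called 5003 genes and fry passed 21 lists. Genes changed at least 2-fold fell from 418 to 62, 160 and 89 with limma on log2(FPKM) at pseudocounts of 1, 0.1 and 0.5, to 57 (quantile), 62 (TMM), 58 (median centred), 61 (no trend) and 57 (robust spread), and to 61 with FPKM of at least 5 in 3 libraries. The pseudocount and the smaller set of genes shrink these counts by construction. That filter tested 6437 genes, left 1474 higher and 3 of the 20 largest changes. Leaving out 1 library gave 2756 to 4640 genes changed by WD6305, 1446 to 2563 higher and 1310 to 2077 lower, each lowest without WD6305 3, and METTL3 log2 fold changes of 0.187 to 0.247, with fewer samples. METTL3 was 0.20 (edgeR adjusted p = 0.0588) in the 4 keratin-carrying libraries, and its adjusted p over all alternatives was 0.00545 to 0.0931. Same-numbered libraries deviated from their group means with correlations of -0.20, 0.065 and -0.13, and not every sample correlated best with its own number. These values give no sign that the numbers pair samples. They cannot exclude it, since deviations from a group mean are tied to each other within a group. The highest correlation, 0.25, was between DMSO 3 and WD6305 1, the libraries without keratin transcripts. The replicate block gave 3204 genes, 1736 higher, 74% of the calls shared, 18 lists and METTL3 at 0.214 (edgeR adjusted p = 0.0584). Camera with an estimated correlation passed 3 lists. The gap between the lowest r within and the highest between groups was 0.0086, and 0.00548 with a pseudocount of 0.1 and 0.0120 with FPKM of at least 5. Medians of lists that had not passed turned sign in some settings, at camera adjusted p of 0.145 or more: m6A erasers and readers to -0.027, -0.017, -0.023, -0.026, -0.016 and -0.042 with limma, -0.077 with FPKM of at least 5, -0.00069 with DESeq2, -0.00067 with RLE, -0.018 with library sizes alone and -0.090 with counts divided by 4; apoptosis to -0.0079, -0.0091, -0.0085, -0.021 and -0.023 with limma, -0.0042 with FPKM of at least 5 and -0.0044 with library sizes alone; erythroid markers (-0.37 over 7 members in edgeR, with 3 members tested by limma on log2(FPKM + 1)) to 0.0060, 0.0019, 0.0051, 0.042 and 0.013 with limma, 0.018 with counts divided by 4 and 0.010 in the 4 libraries. NF-kB genes reached -0.0098 with no filter, reported m6A-regulated genes 0.011 with FPKM of at least 5 and 0.00097 with the block, and HOXA genes -0.0065 with quantile scaling, which also gave -0.10 for mitochondrially encoded genes, -0.14 for MT-CO1 and -0.10 for MT-ND2 (limma adjusted p = 0.0120). Leaving out 1 library gave medians of -0.048 to 0.053 (erasers and readers), -0.048 to 0.045 (m6A-regulated), -0.0098 to 0.090 (HOXA), -0.030 to 0.054 (NF-kB), -0.090 to 0.024 (immediate early) and -0.24 to 0.045 (hypoxia).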

Other observations

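The tests of keratin transcripts as reads from a squamous source and as a response to WD6305, and the motif and length slopes per library, were chosen after the result was seen, as were the annotated terms described first. Of 3827 annotated terms, 351 passed camera at the preset correlation, 131 higher and 220 lower, and 0 passed with an estimated correlation, so the terms serve as descriptions. The subunits of the CCT chaperonin, which folds actin and tubulin, fell together: the term holding them had 9 of 10 genes lower and 0 higher, with log2 fold changes of -0.69 for CCT4, -0.53 for CCT6A, -0.52 for TCP1 and -0.46 for CCT3. Only 1 gene of that term was in a list fixed beforehand. Genes of the term for aminoacyl-tRNA synthesis, mostly synthetases, fell in 22 of 44 and 1 rose, with FARSB at -0.64, VARS1 at -0.56, YARS1 at -0.49 and IARS1 at -0.45. Genes of the term for RNA polymerase complexes, which also holds primases and associated proteins, fell in 19 of 40 and 0 rose, with POLR1E at -0.79, POLR2F at -0.64 and POLR3K at -0.52.

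Glycan-degrading enzymes rose in 10 of 16 genes and 0 fell, with MANBA at 0.89, MAN2B2 at 0.70 and FUCA2 at 0.58. Specific granule membrane genes rose in 35 of 85 and fell in 9. CLEC12A, BST1 and SLCO4C1 had log2 fold changes of 1.34, 1.15 and 0.92. Of 31 genes in the term for cytokine binding, 11 rose and 1 fell. The receptors CXCR4, IL13RA1 and IL6R rose by 0.64, 0.58 and 0.38. Apart from these receptors, ANPEP, the surface peptidase CD13 of myeloid cells, rose by 1.34. All these genes were named after their values were seen, and each passed the edgeR test over all genes.

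Squamous keratin transcripts were present in 4 of the 6 libraries. Of 35 keratinocyte markers with at least 50 counts in a library, 29 were higher in each of DMSO 1, DMSO 2, WD6305 2 and WD6305 3 than in DMSO 3 and WD6305 1, 19 of them over 5-fold, with KRT5, KRT17 and KRT6A the most abundant, while IL1RN, at 42.9 to 50.1 CPM in all 6 libraries, did not separate. The split was found from 9 markers, and of the 26 others 20, or 76.9%, separated, against 5.21% of 15047 genes, which lies between the 80% set for a squamous source and the 50% set against it. Each group holds 2 libraries with and 1 without these transcripts, which argues against a response to WD6305 as the cause of the split. It also means that a batch following the split is shared by the groups. Within the 4 libraries the median absolute log2 ratio between WD6305 and DMSO was 0.26. The markers were picked for being high in all 4, which limits what that ratio can show. RNA or reads from squamous epithelial material may have entered these 4 libraries, as a hypothesis these values leave open, while fibroblast markers in WD6305 1, with 17 of 27 at least 1.5-fold above every other library, were not tested for a cause.

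Granule, lysosome and class II lists rose while MYC-target and proteasome lists fell. After a correction of each library for GC content and transcript length, all 5 passed camera at the preset correlation in the same direction and the lowest share of a median log2 fold change kept was 95.8%. Without the 100 genes with the highest counts, which took 21.9% to 24.3% of a library, all 5 again passed. List members among those 100 genes were left out too, so the medians before and after may cover different genes. The lowest ratio of the median after to the median before was 86.7%, for the granule list. These values argue against either trend as the whole cause. The lysosome and proteasome lists did not pass with an estimated correlation (camera adjusted p = 0.155 for each). A shift of growth and differentiation programmes under WD6305 stays a hypothesis without a test of its own, found on the same data. The data used here hold no measurement of METTL3 protein or m6A.

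If loss of m6A stabilised methylated messages, genes with more DRACH motifs away from exon junctions would be higher under WD6305. Across 13398 genes, which are not independent replicates, the partial Spearman correlation of the log2 fold change with motif number, holding length, GC content and expression, was 0.076 (bootstrap interval over genes 0.0589 to 0.0932, and 0.0572 to 0.0863 without 1 library), which met the bound set before the result was seen, while the 9 other splits, which keep part of the treatment difference, gave 0.0043 to 0.12, with 4 above 0.076. Slopes on motif number taken per library were higher in every WD6305 library than in every DMSO library (t-test p = 0.0147, exact permutation p = 0.1, the smallest 3 against 3 allows), with an interval between libraries of 0.025 to 0.13 on the scale of the correlation. Transcript length alone is argued against by a correlation of -0.055 holding motifs, with an interval between libraries of -0.14 to 0.029, under the 0.05 set beforehand. Without holding other features the correlation was 0.124 with motifs, 0.0677 with length and -0.194 with GC content. The correlation with length was thus above 0 and turned sign when motifs, GC content and expression were held. Loss of m6A may thus account for a small part as a hypothesis, other features of these transcripts stay open, and the data used here hold no m6A measurement.

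With 3 libraries per group there are 10 splits into 3 and 3, too few for a share under 0.05. For genes changed by WD6305 the real split gave 4249 and the highest of the others 3, so 1 split reached the real count, the real one itself. For gene list tests the real split gave 16 lists past the camera threshold and the highest of the others 10, with 1 split reaching 16. The other 9 splits passed 6 to 10 lists each. Each of them mixes the groups unevenly, so by design it keeps part of any difference between WD6305 and DMSO. Their log2 fold changes correlated with the real ones at 0.45 to 0.56 (Spearman), which the shared libraries would partly give without an effect of WD6305. Whether their 6 to 10 lists reflect that difference or correlation between genes, which the preset value may understate, cannot be told from these values.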
